A study of Mus musculus with 6 samples.

How the data were processed

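Gastrocnemius muscle of NSG mice was profiled by RNA sequencing in 3 control and 3 radiotherapy samples, grouped by the treatment given in the labels. Libraries were made from total RNA with a TruSeq RNA kit, per the labels' protocols. The authors deposited 1 table of TPM values, with 57010 Ensembl gene identifiers and 1 column per sample. The tools named are HISAT2, StringTie and RSEM with genome build mm9, per the submitters' processing notes; their versions and roles, the annotation release, strandedness and read filters are not given in the sources used here. Of the identifiers, 52029 are in the GENCODE M21 names and 4981 are not, so the annotation differs from that build's own and no coordinates are given. Gene symbols came from the table itself, and 1606 genes have none.

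TPM is scaled to the same total, 1000000, in each library, which removes depth. Each deposited column summed to that total within 1, so total reads, counting intervals and detection limits were unknown. Because TPM is relative, a larger share of some transcripts lowers all others, and alternative scalings were run for that reason. Reads of near-identical genes, such as globins, mitochondrial genes with nuclear copies and pseudogenes, may have been divided between copies in ways the table does not show, and overlapping genes cannot be separated without strand information.

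Values were transformed to log2(TPM + 1), with a pseudocount of 1, so fold changes of low genes are understated. Fold changes on this scale are radiotherapy minus control. Genes with at least 1 TPM in at least 3 of the 6 samples were tested, 11375 in all. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided) with the group as its only term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. No count model was used, since the values are not counts. Shares of TPM per library were compared by exact two-sided permutation tests, for which 3 samples against 3 cannot give a p below 0.1; 7 such measures were computed and their p-values were not adjusted. No pair of libraries was identical: at most 3.35% of nonzero values were equal to the second decimal in any pair.

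Before the data were examined, 41 gene lists were fixed (668 members, 666 of them in the table, 553 tested), covering matrix and TGF-β genes, muscle fibre types, atrophy, metabolism, stress and polyamine genes, and markers of other cell types. Lists with at least 3 tested members, 39 in number, were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over lists. Members past the threshold were counted both over all genes tested and adjusted over the list alone. Camera with an estimated correlation and the rotation test fry were run beside it. The named genes followed a rule fixed at the same time. It took up to 8 genes per direction among those past the threshold whose groups did not overlap and whose higher mean was at least 1 TPM, leaving out predicted and clone-named genes. With fewer than 5 such genes, it took the 8 of smallest p in each direction, as was the case here. A fixed panel (Srm, Col1a1, Col3a1, Fn1, Acta2, Tgfb1, Ccn2, Cdkn1a, Trim63, Fbxo32), the polyamine genes and up to 4 members of each list were added.

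The gene test was tested on simulated data with 11375 genes drawn independently, of which 100 were changed 2-fold and 100 changed 4-fold. Changed genes were taken from those with a mean log2(TPM + 1) above 2. Of the changed genes, 15 and 91 were recovered, and 5 unchanged genes were called. The list test was tested on 100 simulated draws with no group effect that kept the gene correlation of the residuals; a median of 17 and a 90th percentile of 22 lists were called, and 96 draws gave at least the 9 called in the data. Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a filter of 5 TPM, median-of-ratios scaling, quantile normalization, removal of the 50 most abundant and the mitochondrial genes with rescaling of the rest, limma without the trend, robust limma, estimated sample weights, the replicate number as a block, each sample left out in turn, and other thresholds. The labels number the replicates of both groups alike but state no pairing, so the main fit had no block. Leaving out control 1 and radiotherapy 2 together, and adjusting over the 537 distinct tested list members, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.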

Results

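RNA sequencing measured gene expression in 6 samples of mouse gastrocnemius, a calf muscle made mostly of fast fibres. The samples came from NSG mice, an immunodeficient strain lacking mature lymphocytes. The mice bore subcutaneous tumours of MDA-MB-231, a human triple-negative breast cancer line, in which Rab27a, a small GTPase of vesicle secretion, had been knocked down. In the radiotherapy group (n = 3) the tumour alone received a single dose of 10 Gy, and the muscle of the opposite side was taken 3 days later. Muscle of mice with untreated tumours formed the control group (n = 3). Expression was given as TPM, a length-corrected share of all transcripts, for 57010 genes, of which 30389 were at 0 in all 6 samples, and 11311 ± 379 control and 11278.7 ± 517 radiotherapy genes reached 1 TPM (mean ± SD, n = 3 each). TPM has the same total in every library by construction, so sequencing depth was unknown. The labels do not say that the 3 samples of a group came from separate mice, so p-values measured only the spread between these samples.

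The comparison of radiotherapy with control asked how a distant muscle responds to irradiation of a Rab27a-depleted tumour, in a series whose title concerns tumour-secreted spermidine synthase and muscle fibrosis. Red blood cell transcripts were lower in the radiotherapy muscles, with haemoglobin mRNAs at 0.490 ± 0.202% of all TPM in control and 0.135 ± 0.0371% after radiotherapy (n = 3 each). Transcripts of the mitochondrial genome were higher, at 10.7 ± 2.39% of TPM in control and 18.6 ± 3.73% after radiotherapy. No gene of either kind passed limma over all genes tested, and both shares gave an exact permutation p of 0.1, the smallest possible. Neither list was called by camera with an estimated correlation (adjusted p = 0.426 and 0.315). No gene of the extracellular matrix, polyamine or muscle atrophy lists passed the test, over all genes or over its list alone; 3 tendon genes, some of which encode matrix proteins, fell when adjusted over the list alone. Several groups of cell type markers were high in 1 library rather than in 1 group.

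No gene passed limma at an adjusted p of 0.05 among the 11375 tested, with 0 higher and 0 lower. At an unadjusted p under 0.05, 110 genes were higher and 325 lower, 435 in all against 569 from chance alone, and the smallest adjusted p was 0.394 (limma, Gm55635). The 3 radiotherapy values lay wholly above or below the 3 control values in 1051 genes, 9.24% of those tested, against 10% by chance. Libraries of the same group were no more alike than libraries of different groups: Pearson's r of log2 values, across genes, averaged 0.948 over 6 pairs within groups and 0.949 over 9 pairs between groups. The first principal component held 30.6% of the variance and set radiotherapy 2 (53.6) apart from control 3 (−34.7). In simulated data of this size, limma recovered 15 of 100 genes changed 2-fold and 91 of 100 changed 4-fold. These genes were drawn independently and changed together, which makes the adjusted threshold easier to pass than where few genes change. The recovered counts therefore do not show that a few 4-fold changes would have been called here. The globin gene Hba-a2, with a log2 fold change of −2.18, did not pass (limma adjusted p = 0.648). Neither did the haptoglobin gene Hp, at 2.32 (limma adjusted p = 0.977). The median log2 fold change of all tested genes was −0.11, with 67.9% of them negative, and it moved to −0.01 with quantile normalization, so medians of gene groups are to be read against that shift.

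Red blood cell genes gave the smallest p-values among genes with established names. Each of the 5 tested members fell when adjusted over the list alone (limma, adjusted p from 0.000427 to 0.000663), and none did when adjusted over all genes tested (adjusted p from 0.648 to 0.977). The β-globin gene Hbb-bs went from 1986.4 ± 850 TPM in control to 552 ± 169 TPM, 3.60-fold lower (log2 fold change −1.81, SE 0.34, n = 3 each). The other adult globins gave log2 fold changes of −1.90 for Hbb-bt, −2.18 for Hba-a2 and −1.54 for Hba-a1; the globin genes are near-identical pairs, so the values of single copies are uncertain. Alas2, the erythroid enzyme that starts haem synthesis, has no such copy and went from 12.4 ± 4.26 TPM to 3.16 ± 1.05 TPM (log2 fold change −1.68, 95% interval −2.37 to −0.98). For each of the 5 genes all 3 radiotherapy values lay below all 3 control values. The list was lower in camera, limma's gene set test (median log2 fold change −1.81, adjusted p = 8.14e-14 with the preset correlation), but not with a correlation estimated from these samples (adjusted p = 0.426 with an estimated correlation). A two-sided exact permutation test of the haemoglobin share gave p = 0.1, the smallest value that 3 samples against 3 allow.

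**Figure D1:**
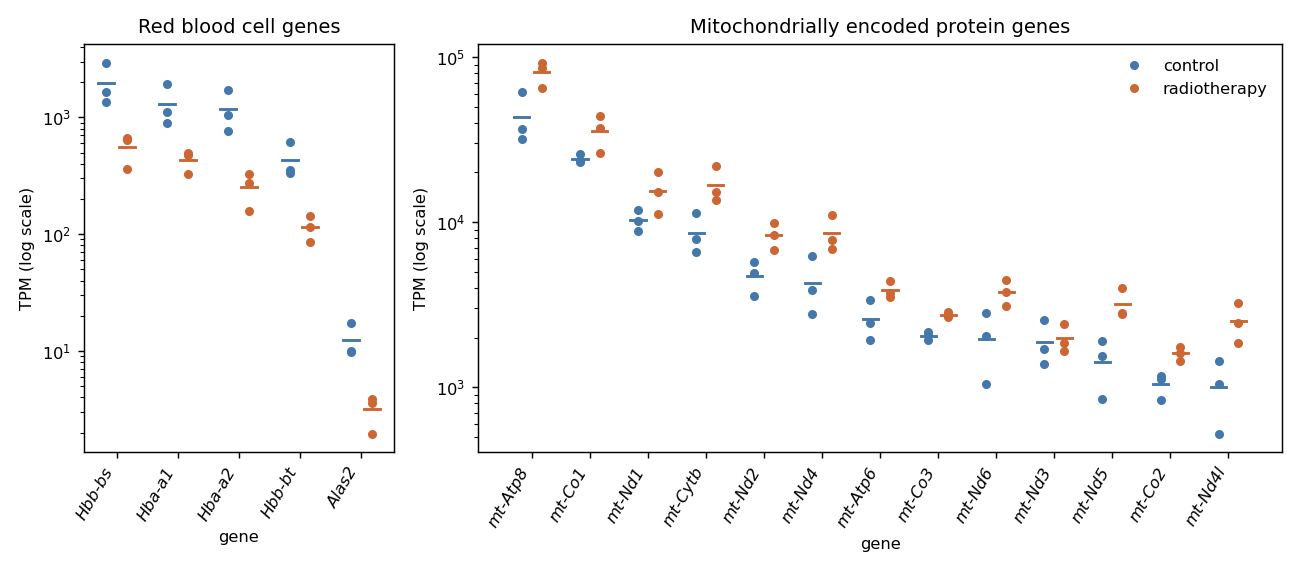
TPM on a log scale of the 5 red blood cell genes (left) and the 13 protein genes of the mitochondrial genome (right). Each point is 1 library, blue for control and orange for radiotherapy (n = 3 each), and bars are group means. For the red blood cell genes the radiotherapy points lie below the control points, and the mitochondrial means are higher after radiotherapy.

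Of the 13 protein genes encoded by the mitochondrial genome, 12 rose when adjusted over the list alone (limma, adjusted p from 0.0122 to 0.0376), and none when adjusted over all genes tested. The cytochrome b gene mt-Cytb went from 8620.3 ± 2473 to 16881 ± 4342 TPM (log2 fold change 0.98, SE 0.24), and mt-Nd5, a complex I subunit, from 1430.7 ± 537 to 3192 ± 685 TPM (1.22, SE 0.30). The complex I gene mt-Nd2 gave 0.82 and the overlapping genes mt-Nd4l and mt-Atp8, whose reads cannot be divided with certainty, gave 1.40 and 0.95. The value of mt-Atp8 went from 43223 ± 15691 to 80964 ± 14123 TPM, so the mitochondrial share of TPM rests in large part on this uncertain gene. The exception was mt-Nd3, with a log2 fold change of 0.11. The list was higher in camera (median 0.82, adjusted p = 1.19e-24), a call lost with an estimated correlation (adjusted p = 0.315 with an estimated correlation). The mitochondrial share of TPM was highest in radiotherapy 2, at 22.2%, and lowest in control 3, at 8.71% (exact permutation p = 0.1, the smallest possible). Radiotherapy 2 held the highest value for 11 of the 13 genes, and without it 0 of them passed over the list alone, although the list median was still 0.69 (camera adjusted p = 2.29e-15). In radiotherapy 1 and 3 the mitochondrial share was 18.7% and 14.8%, above the 13.4% of control 2, the highest control, and for 11 of the 13 genes all radiotherapy values lay above all control values. None passed over the list alone when genes of low expression were kept in the test. Nuclear genes of oxidative phosphorylation, which include subunits of the same complexes, had a median of −0.14 over 47 tested members and no call (camera adjusted p = 0.375). They were called lower without a filter (0.0103), without control 2 (0.0317) and without radiotherapy 2 (0.000372), and higher without radiotherapy 3 (0.00352) and with sample weights (0.00112), all camera adjusted p. Their median was within 0.03 of 0 under each of 3 other scalings and turned positive, at 0.01, with quantile normalization. Sample weights, here and below, gave radiotherapy 1 a weight of 31.2 against 0.329 and 0.235 for radiotherapy 2 and 3. The estimation of these weights stopped before it converged, so results with sample weights rest largely on radiotherapy 1.

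Most contractile and glycolytic genes of fast fibres had lower values after radiotherapy. The 13 fast fibre genes together made up 15.1 ± 0.772% of TPM in control and 11.1 ± 2.57% after radiotherapy (exact permutation p = 0.1). The lowest share, 8.26%, was in radiotherapy 2. Mitochondrial and near-identical predicted genes took 20.8 to 26.8% of TPM in controls and 27.5 to 42.5% after radiotherapy. That lowers the share of every other gene, so part of this drop follows from TPM being relative. After median-of-ratios scaling the fast fibre median was −0.35, against −0.50 before. Atp2a1, the calcium pump of the fast sarcoplasmic reticulum, had a log2 fold change of −0.69 (SE 0.22), and Mylpf, a fast myosin light chain, one of −0.49 (SE 0.16), but 0 of the 13 passed over the list alone. Of the 13, 11 were negative, while the fast myosins Myh1 and Myh2 gave 0.54 (SE 0.39) and 0.61 (SE 0.49). The list median was −0.50 (camera adjusted p = 8.66e-05; adjusted p = 0.643 with an estimated correlation). Its call ended without radiotherapy 3 (camera adjusted p = 0.191) and with sample weights (camera adjusted p = 0.377). Leaving out the 50 most abundant genes removed 9 of the 13 members, so that setting did not test the list. Glycolysis and glycogen genes were lower too (median −0.67, camera adjusted p = 1.41e-05; adjusted p = 0.643 with an estimated correlation), with 0 of 15 members past the test over the list alone and no call with sample weights (camera adjusted p = 0.338). Without radiotherapy 2 the glycolysis median was −0.36 (camera adjusted p = 2.48e-06). Among them, Ldha, which reduces pyruvate to lactate, went from 2265.8 ± 170 to 1216.4 ± 609 TPM (log2 fold change −1.06, SE 0.39), and Pfkfb3, a regulator of glycolytic flux, gave −1.54. The slow fibre list was higher (median 0.35, camera adjusted p = 3.02e-05; adjusted p = 0.825 with an estimated correlation), with 187 ± 78.8 and 278 ± 28.6 TPM for the slow myosin Myh7 (log2 fold change 0.66, SE 0.31), and none of 10 members past the test. The level of control 1 lay above those of the 3 radiotherapy libraries, control 1 was highest for 6 of the 10, and without control 3, the lowest library, the slow fibre median was 0.07 (camera adjusted p = 0.196). The 73 cytosolic ribosomal protein genes had a median of −0.22 (camera adjusted p = 7.76e-05; adjusted p = 0.933 with an estimated correlation), led by Rps15a (−0.71, SE 0.21). That call ended after median-of-ratios scaling (camera adjusted p = 0.0764), after quantile normalization (0.105), with sample weights (0.220), without control 3 (0.106) and without radiotherapy 3 (0.191).

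The genes of fibrosis did not separate the groups. Of 17 tested extracellular matrix genes none passed over the list alone, and the median was −0.08 (camera adjusted p = 0.375), a value that turned positive under each of 3 other scalings. Col1a1, the main fibrillar collagen gene, was at 3.68 ± 3.44 TPM in control and 2.71 ± 1.67 TPM after radiotherapy (log2 fold change −0.17, 95% interval −1.29 to 0.95). Col3a1 gave 0.09, with an interval from −1.86 to 2.04, and its highest value, 33.7 TPM, was in control 1. Fibronectin (Fn1) gave −0.08 (SE 0.35) and Acta2, the smooth muscle actin of myofibroblasts, 0.38 (SE 0.30). Among 14 genes of the TGF-β response the median was −0.31 (camera adjusted p = 0.698; 0.00560 without control 3, and a median of −0.07 without control 1), with −0.43 for Tgfb1 and −0.54 for its target Ccn2. Matrix proteases and their inhibitors had a median of 0.04 over 8 genes (camera adjusted p = 0.470; 0.0350 without control 1, and a median of −0.17 without radiotherapy 3), and markers of fibro-adipogenic progenitors, the matrix-producing cells of muscle, one of −0.08 over 10 (camera adjusted p = 0.798; 0.00658 and higher without control 1). Control 1 held the highest value for 13 of the 17 matrix genes and 8 of the 10 progenitor markers, and it was also the library with the most leukocyte transcripts. Without control 1 the matrix list was called higher (camera adjusted p = 1.48e-05), and without control 3 it was called lower (camera adjusted p = 0.0382). Tendon genes were an exception among connective tissue lists: the 3 that were tested fell when adjusted over the list alone (limma, adjusted p from 0.00534 to 0.0469). Scx, a tendon transcription factor, went from 7.28 ± 0.855 to 3.28 ± 0.941 TPM (log2 fold change −0.97), and Fmod, a collagen-binding proteoglycan, from 9.28 ± 5.07 to 2.34 ± 0.400 TPM (−1.50). The tendon list was lower in camera (adjusted p = 8.66e-05; adjusted p = 0.498 with an estimated correlation), and the other 6 of its 9 members were below the expression filter. No tendon gene passed over all genes tested, nor over the 537 distinct list members together (lowest limma adjusted p = 0.190, Fmod).

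**Figure D2:**
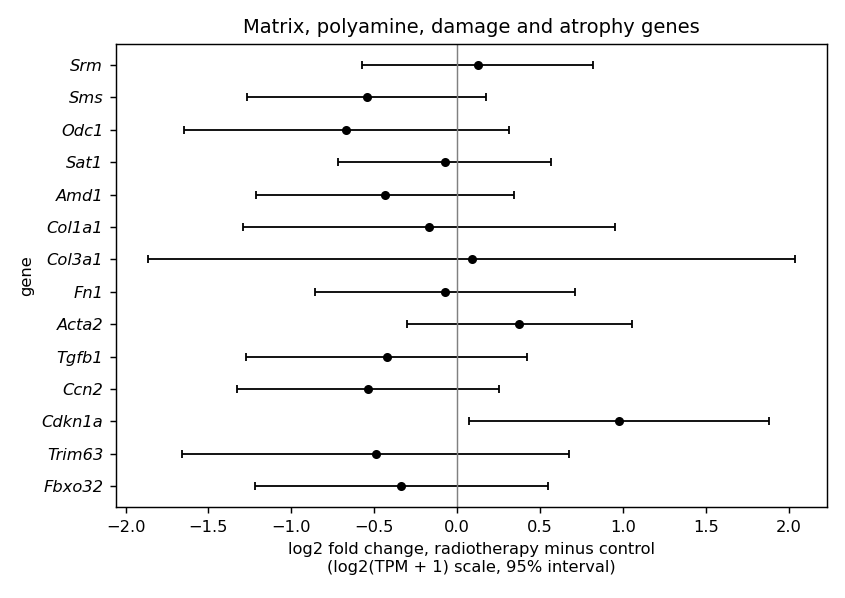
Log2 fold changes (radiotherapy minus control, on the log2(TPM + 1) scale) of 14 matrix, polyamine, damage and atrophy genes. Points are limma estimates and bars 95% intervals (n = 3 per group, no adjustment for the number of genes). Each interval except that of Cdkn1a, 0.07 to 1.88, includes 0.

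Polyamine genes were examined because tumour-secreted spermidine synthase is named in the title of the series. Mouse muscle mRNA does not measure what the human tumour secreted, and no sample here came from a mouse whose tumour lacked the knockdown. Srm, the mouse gene of spermidine synthase, was at 6.12 ± 1.10 TPM in control and 7.09 ± 3.25 TPM after radiotherapy (log2 fold change 0.12, 95% interval −0.57 to 0.82). Values for the enzymes around it were −0.67 (SE 0.43) for Odc1, which makes putrescine, −0.43 (SE 0.34) for Amd1, −0.54 (SE 0.32) for the spermine synthase Sms and −0.08 (SE 0.28) for the acetyltransferase Sat1. Of the 15 tested polyamine genes, 12 had negative values (median −0.34, camera adjusted p = 0.0811; 0.0453 without radiotherapy 1 and 0.0394 without a filter, and a median of −0.16 without radiotherapy 2), with the spermine oxidase Smox at −0.94 and the antizyme Oaz1 at −0.79, and none passed over the list alone. The knockdown of Rab27a was in the human tumour cells of both groups, so the mouse gene does not check a label. It lay under the expression filter, at 1.09, 1.09 and 0.66 TPM in controls 1, 2 and 3 and at 0.37, 0.53 and 0.73 TPM in radiotherapy 1, 2 and 3 (log2 fold change −0.33, SE 0.18, limma adjusted p = 0.895 without the filter).

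No gene of the DNA damage, atrophy and stress lists passed limma, and camera called none of these lists with the settings fixed as the main ones, though other settings called several. Cdkn1a, the p53 target that arrests the cell cycle, had a log2 fold change of 0.98 (SE 0.40, limma adjusted p = 0.977). Its TPM was 141, 150 and 165 in the radiotherapy libraries and 52.3, 54.0 and 158 in the controls. The 17 p53 targets together had a median of 0.06 (camera adjusted p = 0.0760), and the 7 tested cell cycle genes one of −0.17 (camera adjusted p = 0.680; 0.0312 without a filter). The p53 list was called higher without control 3 (camera adjusted p = 3.37e-06), without radiotherapy 3 (1.63e-05) and with sample weights (4.21e-07), but its median was −0.12 without control 1 (0.997), −0.04 without control 2 (0.346) and −0.02 without radiotherapy 2 (0.641). The ubiquitin ligases of muscle atrophy gave −0.49 for Trim63 (SE 0.52) and −0.34 for Fbxo32 (SE 0.39). The atrophy list of 11 genes was negative throughout (median −0.31, camera adjusted p = 0.0811), led by myostatin, Mstn, at −1.05 (SE 0.37), and control 3 held the highest value for 9 of the 11. It was called lower without control 1 (camera adjusted p = 4.84e-05), without radiotherapy 2 (0.00267), without a filter (0.0312) and with sample weights (0.00226), but its median was −0.08 without control 3 (0.914) and −0.12 without radiotherapy 1 (0.600). The 12 glucocorticoid response genes had a median of −0.35 (camera adjusted p = 0.451) and were called lower without control 1 (0.0191), without radiotherapy 2 (0.0104) and with sample weights (0.000560). Without radiotherapy 1 the glucocorticoid median was −0.07 (camera adjusted p = 0.413), and the list mean relative to other genes was then 0.17, as it was 0.03 without control 3. The median was −0.17 for 13 autophagy and lysosome genes (camera adjusted p = 0.825). That autophagy median was 0.03 without radiotherapy 2, −0.07 without control 3 and −0.37 without radiotherapy 3. The 16 immediate early genes had a median of −0.38 (camera adjusted p = 0.126) and were called lower without control 3 (1.13e-09) and without radiotherapy 1 (0.0168), but their median was −0.18 without control 1 (0.997). The circadian list had a median of −0.27 over 14 genes (camera adjusted p = 0.375; 0.0191 without control 1, and a median of −0.03 without control 2), with the clock output gene Dbp at −1.22 (SE 0.37). Chac1, a target of the integrated stress response, gave −1.76 (SE 0.52) within a list of 15 whose median was −0.04 (camera adjusted p = 0.790).

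For the remaining muscle and metabolic lists no member passed over the list alone. The proteasome list had a median of −0.00 over 31 genes (camera adjusted p = 0.186), and radiotherapy 3 held the highest value for 28 of them. It was called higher after median-of-ratios scaling (camera adjusted p = 0.0418), after quantile normalization (0.0110), and without control 3 (0.00560), radiotherapy 1 (0.0456) or radiotherapy 2 (0.00221), but without radiotherapy 3 its median was −0.25 (0.322). Medians were −0.07 for 11 heat shock genes (camera adjusted p = 0.798; lower at 0.0382 without control 3 and 0.0328 with sample weights), −0.03 for 10 lipid and sterol synthesis genes (camera adjusted p = 0.438) and −0.01 for 6 myogenic differentiation genes (camera adjusted p = 0.438). The signs of these medians, like that of the integrated stress response, turned under each of 3 other scalings. Fatty acid oxidation genes had a median of 0.05 and a mean of −0.08 over 18 members (camera adjusted p = 0.400), with Ucp3 at −1.37 and Pdk4 at −1.15. Their median was −0.29 without radiotherapy 3, which was highest for 10 of the 18, and 0.19 without radiotherapy 1. The 13 antioxidant genes had a median of 0.19 (camera adjusted p = 0.0758), and radiotherapy 3 was highest for 11 of them. They were called higher after quantile normalization (camera adjusted p = 0.0464) and without control 1 (0.0291), radiotherapy 1 (0.00893) or radiotherapy 2 (0.0104), but without radiotherapy 3 their median was −0.13 (0.920). Denervation genes had a median of −0.12 over 6 (camera adjusted p = 0.827) and satellite cell genes one of −0.06 over 3 (camera adjusted p = 0.790). Both medians were 0.02 after median-of-ratios scaling. They were 0.02 and −0.05 after quantile normalization, and −0.01 and −0.18 after rescaling without the abundant genes.

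Markers of other cells differed between libraries within a group. Adipocyte genes were higher in camera (median 1.23, adjusted p = 1.11e-06; adjusted p = 0.643 with an estimated correlation), and radiotherapy 1 held the highest value for 8 of 8. Without radiotherapy 1 the adipocyte median was 0.48 (camera adjusted p = 0.00931) and without control 3 it was 0.60 (0.00213), and the list level of control 2 lay above those of radiotherapy 2 and 3. Cfd, the adipokine adipsin, stood at 1412.2 TPM in radiotherapy 1 and between 24.4 and 250.2 TPM in the other 5 libraries. Schwann cell genes were higher as well (median 1.17, camera adjusted p = 1.17e-06; adjusted p = 0.643 with an estimated correlation). With sample weights, which rest largely on radiotherapy 1, the direction turned and the call was lost (camera adjusted p = 0.908). Radiotherapy 3 was highest for 7 of 7. The list levels, minus the control mean, were −0.42, 0.69 and −0.27 in controls 1, 2 and 3 and −0.42, 1.17 and 2.61 in radiotherapy 1, 2 and 3, and without radiotherapy 3 the Schwann cell median was 0.35 (camera adjusted p = 0.000539). Neutrophil genes had a median of −0.90 over 7 (camera adjusted p = 0.0758), and control 1 was highest for all 7, with 859 TPM of S100a9. The neutrophil list was called lower after median-of-ratios scaling (camera adjusted p = 0.0455), quantile normalization (0.0386) and rescaling without the abundant genes (0.0273), with sample weights (0.0439), and without control 2 (0.00109), control 3 (0.000257) or radiotherapy 3 (0.0350). Without control 1 its median was −0.15 (camera adjusted p = 0.849). Control 1 was also highest for 9 of 11 macrophage genes (median −0.41, camera adjusted p = 0.790), 18 of 18 type I interferon genes (median −0.02, camera adjusted p = 0.400) and 13 of 13 antigen presentation genes (median −0.24, camera adjusted p = 0.792). Without control 1 the macrophage (camera adjusted p = 0.00144), antigen presentation (9.90e-06) and interferon lists (8.19e-12) were called higher. Without control 3 the macrophage (0.00418) and antigen presentation lists (0.00256) were called lower, as was the macrophage list with sample weights (0.0427). The interferon list was called lower without control 2 (0.0156) and higher without radiotherapy 3 (0.00352) and with sample weights (0.0244), and its median turned positive under each of 3 other scalings. The 13 STAT3 and acute phase genes had a median of 0.19 (camera adjusted p = 0.0758; 0.0151 without control 1 and 7.66e-05 without radiotherapy 1), and 8 inflammatory cytokine and NF-kB genes one of 0.18 (camera adjusted p = 0.352; 0.000145 without control 1 and 0.0250 without radiotherapy 1). Both medians turned negative without radiotherapy 3, at −0.11 (camera adjusted p = 0.406) and −0.22 (0.989), and the inflammatory one also without control 3 (−0.21) and control 2 (−0.05). Endothelial genes had a median of 0.04 over 11 (camera adjusted p = 0.0758) and were called higher after quantile normalization (0.0278), with a filter of 5 TPM (0.0325) and without control 1 (0.0114). Pericyte and smooth muscle genes had one of 0.04 over 10 (camera adjusted p = 0.0811; 0.0306 without control 1 and 0.0383 without radiotherapy 2), with Cnn1 at 0.79 (SE 0.24). Without radiotherapy 3 these 2 medians were −0.09 and −0.15, and without control 3 they were −0.09 and −0.03. None of the 13 lymphocyte genes reached the filter, the highest value being 0.74 TPM for Cd79b in control 1, and of the 9 skin epithelium genes only Krt10 was tested (log2 fold change −0.19). In all, camera called 4 lists higher and 5 lower of 39 tested, but 100 simulated draws with no group effect and the gene correlation of these libraries gave a median of 17 called lists. With an estimated correlation, and with the rotation test fry, 0 lists were called.

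**Figure D3:**
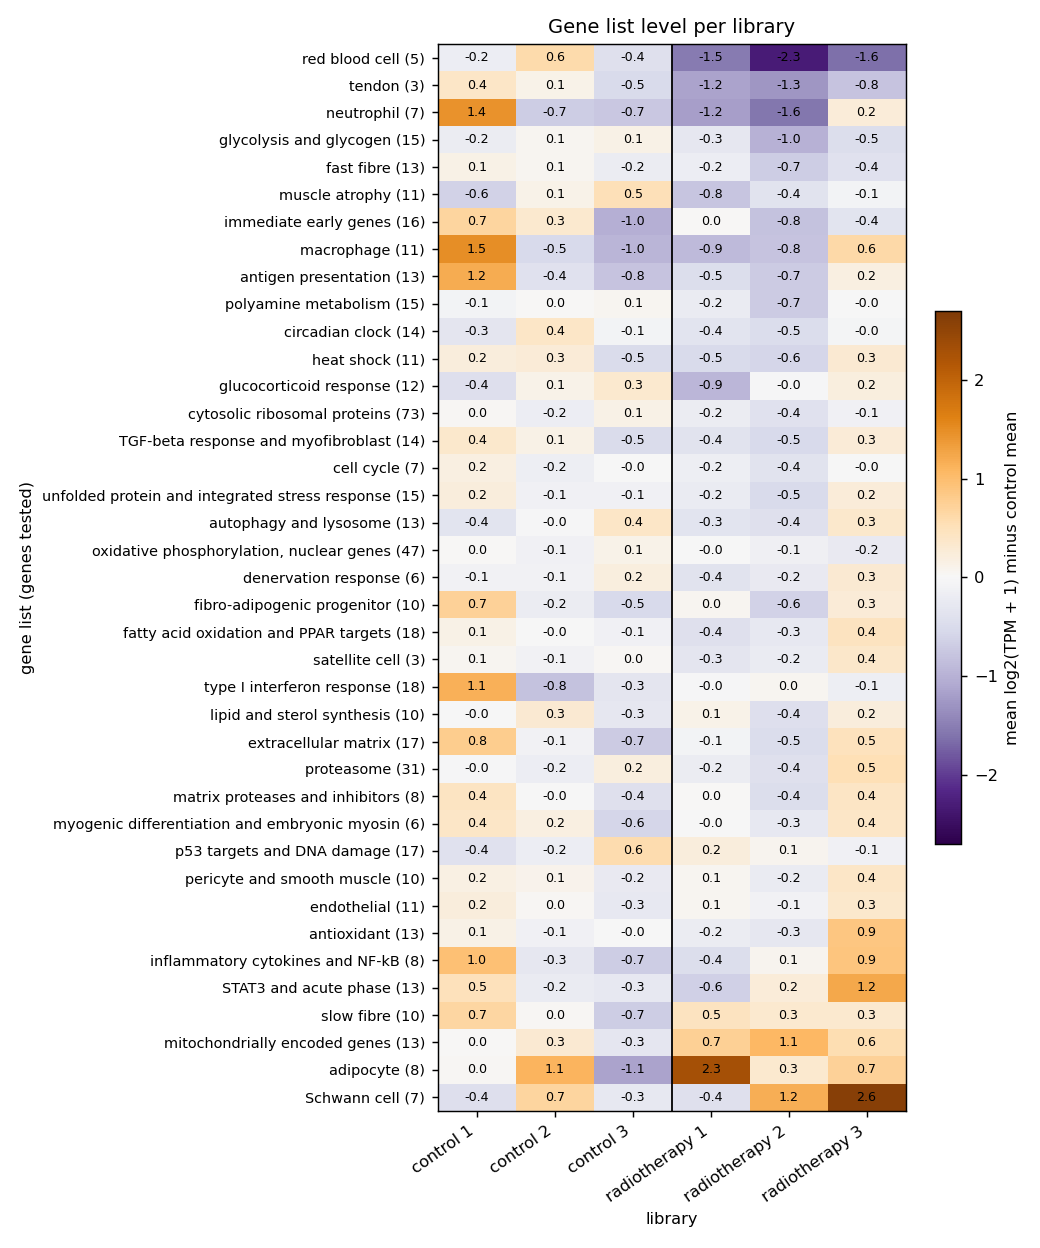
Mean log2(TPM + 1) of each tested gene list in each of the 6 libraries, minus the mean of the 3 controls. Orange is above and purple below the control mean, numbers in brackets count the tested genes, and lists are ordered by the difference between groups. Red blood cell genes are low in the 3 radiotherapy libraries, whereas adipocyte and neutrophil genes stand out in single libraries and Schwann cell genes in radiotherapy 3 and, by less, radiotherapy 2.

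Beyond the red blood cell and mitochondrial genes, the genes with the smallest p-values in each direction did not pass limma (adjusted p = 0.977 for each gene named here). Hp, the haptoglobin gene, whose product binds free haemoglobin, went from 19.6 ± 13.6 to 87.0 ± 28.6 TPM (log2 fold change 2.32, SE 0.55). Tnfrsf4, a receptor of activated T cells, gave 0.85 (SE 0.20), with means of 0.717 and 2.08 TPM, and Izumo4 gave 0.85 (SE 0.23). Among lower values, Odf3l2 gave −1.97 (SE 0.44) and Wdr25 −0.98 (SE 0.22). Rps13-ps1, a ribosomal protein pseudogene that may share reads with its parent gene, gave −1.36 (SE 0.30).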

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

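The setting that left out control 1 and radiotherapy 2 together was chosen after the data were seen. The count of 0 genes in limma held under every alternative run except sample weights, which called 1 gene (ENSMUSG00000120158, which has no symbol in the table; 2159 at an unadjusted p under 0.05), and the fit without control 1. Leaving out 1 sample in turn gave 0 to 6 genes, the 6 being Gm43778, Gm55635 and 4 Snord3b copies without control 1. Robust limma, limma without the trend and the fit without a filter called 0 genes, with 459, 434 and 862 at an unadjusted p under 0.05. The 9 called lists became 11 to 23 with 1 sample left out, 23 without control 1 and radiotherapy 2, and 0 both with an estimated correlation and with fry; robust limma has no list test. The red blood cell count over the list alone was 5 in each alternative but the fit without a filter, where it was 6, and no polyamine gene passed in any. The mitochondrial count of 12 was 0 without the filter, 0 to 11 with 1 sample left out (0 without radiotherapy 2, 7 without radiotherapy 1) and 2 without control 1 and radiotherapy 2. The tendon count of 3 was 2 or 3 with 1 sample left out and 1 without control 1 and radiotherapy 2. The causes were not tested, beyond fewer samples in those fits.

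Of the 30 lists not called, 22 were called in at least 1 fit with 1 sample left out and 13 under another setting with all 6 samples. Some list means, relative to the other tested genes, changed sign with the libraries used. Without control 1 they were 0.36 for fibro-adipogenic progenitors, 0.54 for macrophages and 0.47 for antigen presentation, and without control 1 and radiotherapy 2 they were 0.51, 0.72 and 0.52. With 1 sample left out in turn, the means ranged from −0.26 (without control 3) to 0.48 (without control 1) for matrix, from −0.26 to 0.36 for progenitors, from −0.72 to 0.54 for macrophages and from −0.61 to 0.47 for antigen presentation, the lowest of these without control 3. They ranged from −0.34 (without control 2) to 0.63 (without control 1) for interferon genes and from −0.13 (without radiotherapy 2) to 0.17 (without radiotherapy 3) for nuclear oxidative phosphorylation. The last was 0.16 with sample weights, and the Schwann cell mean was −0.38 with sample weights. Those weights gave radiotherapy 1 a weight of 31.2 against at most 1.12 for the others, and their estimation stopped before it converged. Adipocyte, tendon, red blood cell and mitochondrial lists kept their camera call in each of the 15 or 16 settings with the preset correlation but lost it with an estimated one (camera adjusted p = 0.643, 0.498, 0.426 and 0.315). Their means nearest to 0 were 0.61, −0.56, −1.37 and 0.65, against 1.22, −0.97, −1.72 and 0.90 with all samples.

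With the replicate number as a replicate block, 0 genes were called (403 at an unadjusted p under 0.05), 11 lists (muscle atrophy, camera adjusted p = 0.00474, and neutrophil, 0.0313, were gained), and 5 red blood cell, 12 mitochondrial and 2 tendon genes over their lists. Deviations from the group means correlated by −0.06, 0.02 and −0.11 between samples of the same number, and no sample correlated best with its own number, so the numbers were not taken as pairs. Depth was unknown, so the precision of low values cannot be given.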

Other observations

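The tests on Alas2, on leukocyte and platelet genes, on summed mitochondrial shares, on nuclear respiratory genes and on other splits of the samples were chosen after the results were seen, as were the noncoding genes and the second red blood cell set named here. The smallest p-value in the table belonged to a predicted gene. This gene, Gm55635, was at 13.4, 25.2 and 29.4 TPM in the radiotherapy libraries and at 2.69, 0 and 0 TPM in the controls (log2 fold change 3.87, limma adjusted p = 0.394). Gm24497 was listed at 0 in each control and at 1.82, 70.0 and 15.9 TPM after radiotherapy. The 4 copies of Snord3b, a small nucleolar RNA of ribosomal RNA processing, had identical values, 33.2, 0 and 0 TPM in controls and 8.35, 2.90 and 12.0 TPM after radiotherapy, so they count as 1 measurement.

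Other genes of red cells were lower by less than the globins. Bpgm, which makes 2,3-bisphosphoglycerate, gave a log2 fold change of −1.03 (SE 0.36) and Fech, the last enzyme of haem synthesis, −0.71 (SE 0.29), while Slc25a37, a mitochondrial iron carrier, gave −0.04 (SE 0.30); muscle expresses these genes too. P-values were also adjusted over the 537 distinct tested list members together, an adjustment added after the data were seen. Hbb-bt and Hba-a2 passed it (limma adjusted p = 0.0459), the only 2 members to do so. Alas2 and Hbb-bs did not pass (limma adjusted p = 0.0612). No mitochondrial or tendon gene passed either, the lowest being Fmod, mt-Cytb and mt-Nd5 (limma adjusted p = 0.190 each). Srxn1, which repairs oxidised peroxiredoxins, was at 64.3 TPM in radiotherapy 3 and between 7.36 and 11.2 TPM in the other 5 libraries, and the acute phase gene Lcn2 at 285 TPM against 25.1 to 71.4 TPM, but Saa3, also an acute phase gene, was at 676 TPM in control 1 and 672 TPM in radiotherapy 3.

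The lower red blood cell transcripts may reflect less blood in the tissue, or blood with fewer young red cells after radiotherapy. The larger mitochondrial share does not account for them: with mitochondrial and the most abundant genes left out and the rest rescaled, their mean log2 difference was −1.74 (SE 0.42) against −1.82 (SE 0.39) before, and 5 of 5 still passed over the list alone. Exchange of reads between globin copies would raise some copies as others fell. It is argued against by the globins, each of which was lower. Their summed share went from 0.490 ± 0.202% of TPM in control to 0.135 ± 0.0371% after radiotherapy. Alas2, which is not a globin, was lower too, at −1.68 (95% interval −2.37 to −0.98). Less residual blood stayed open, because 4 leukocyte and platelet genes had a mean of −0.57 with an interval from −2.77 to 1.64, which includes both 0 and the red cell value. This test could decide little, since S100a8 and S100a9, among the 4, stood at 652 and 859 TPM in control 1, the library high in leukocyte genes. The platelet genes Pf4 and Itga2b gave 0.05 (SE 0.54) and −0.32 (SE 0.30), but Itga2b reached at most 1.83 TPM. An effect of radiotherapy on circulating red cells, the biological alternative in this design, was not tested.

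The higher mitochondrial transcripts are a second pattern. Exchange of reads with near-identical predicted genes was examined by the summed share of both. The sum was 23.0% of TPM in control and 34.7% after radiotherapy, a difference of 11.7 points (SE 4.74). Because TPM is length-corrected, exchange between genes of unequal length would also change this sum, so the sum cannot exclude exchange. The predicted genes alone held 12.3 ± 1.10% of TPM in control and 16.1 ± 3.82% after radiotherapy. A rise of the whole respiratory chain is argued against by its nuclear genes, whose mean log2 difference was −0.13 (SE 0.095) against 0.79 (SE 0.23) for the mitochondrial genes. Relative to the other tested genes these means were −0.02 and 0.90. With 1 sample left out, the relative nuclear mean ranged from −0.13 (without radiotherapy 2, called lower) to 0.17 (without radiotherapy 3, called higher). The mitochondrial mean was 0.65 and 1.15 in these 2 fits. RNA quality and library preparation could also set the mitochondrial share and were not tested, and radiotherapy itself stays open. Without radiotherapy 2, 0 genes passed over the list alone, but the list median was 0.69 against 0.82 with it.

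Single libraries may contain neighbouring tissue or other cells. In second marker sets written before their values were seen, with no gene of the first lists, 9 of 9 myelin genes were highest in radiotherapy 3 (exact binomial p = 9.92e-08 against 1 in 6), in line with nerve in that sample. Likewise 7 of 11 adipocyte genes were highest in radiotherapy 1 (exact binomial p = 0.000629) and 12 of 12 leukocyte genes in control 1 (exact binomial p = 4.59e-10). Genes of a set vary together, so these p-values are too small. The called adipocyte and Schwann cell lists therefore may describe how samples were dissected, although a response of those cells was not tested, and the Schwann cell level of radiotherapy 2, at 1.17, also lay above each control.

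The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes and the highest other 15. All 10 splits gave at least as many genes as the real one, which a count of 0 fixes in advance. For lists the real split gave 9 and the highest other 23, and 9 of the 10 splits gave as many. Over the list alone, the real split gave 5 red blood cell genes (highest other 0), 12 mitochondrial genes (highest other 0) and 3 tendon genes (highest other 1). Each of these counts was reached in 1 of the 10 splits. These 3 lists were picked because their members passed in the real split, so that split was favoured in advance. Other lists were not counted this way, so these counts do not argue against chance. At an unadjusted p under 0.05 the real split gave 435 genes and the others 175 to 1123, so splits that ignore the treatment can part the libraries more strongly than the treatment does.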
